A study of Mus musculus with 23 samples.

How the data were processed

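Gene expression was measured in scrapings of the small intestine from 23 male C57BL/6J mice with 2-colour Agilent oligonucleotide arrays, 1 array per mouse. Per the labels' protocols, all mice had a normal-fat diet for 3 weeks and then a high-fat diet for 12 weeks, either alone (HF, 12 mice) or with 0.33% quercetin by weight (HF-Q, 11 mice), and were fasted for 2 to 4 hours before tissue was taken. The series began with 24 mice, and a quercetin-fed mouse with an abscess was left out by the authors. Per the labels' protocols, 200 ng of total RNA per mouse was amplified and labelled with both dyes. The Cy5 product of each mouse was hybridised against an equimolar Cy3 pool of all mice, with no dye swap. A protocol field names liver as the tissue of RNA extraction, against every other label of these samples, and markers of hepatocytes were therefore examined.

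Each array had 1 scanner output file. Per the file headers and the submitters' processing notes, the spots were read with Agilent Feature Extraction 10.7.3.1, and the spot and background columns used here are intensity values on a linear scale with no normalization between arrays. The files also hold the authors' log10 ratio of Cy5 over Cy3 from the same software, already background-subtracted and dye-normalized per the file headers, which was used in 1 alternative. A further table of the authors holds processed log2 values for 31718 spots (29141 probes). Set against the scanner values, those log2 values are Cy5 signals with the deviation of the Cy3 pool taken off, since the slope on Cy5 was 0.990 to 1.00 and the slope on Cy3 was -1.04 to -0.970 over the arrays. Their direction is that of Cy5, the median of each column was 9.11, and the method used to reach that common median is not given in the sources used here. Deviations of that table from the gene means correlated with the log2 ratios computed here at 0.863 to 0.966 across genes, which are not independent replicates.

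Values were computed with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50 on the mean spot and median background signals, arrays were normalized by loess within each array with the 3671 control spots at weight 0, and log2(Cy5/Cy3) was taken. Spots marked as outliers by the scanner software in either channel (260 to 355 per array) were set to missing, and spots of the same probe were averaged. A probe was kept when its Cy5 signal was well above background on at least 50% of the arrays of either diet. This left 29249 of 55681 probes (52.5%). Of a gene's probes, the one with the brightest mean Cy5 signal over all arrays was used, chosen without regard to diet.

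Gene names came from a RefSeq table of mouse assembly GRCm38.p6, through the transcript accession for 27235 probes, the symbol for 3581 and a synonym for 565. The remaining 24300 probes kept the name in the scanner file. Positions are those of the probes in the scanner files, on genome build mm9. No coordinates of the RefSeq table were used, and exon or intron positions of the probes were not analysed here.

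HF-Q was compared with HF by lmFit and eBayes of limma over all 23 arrays with no covariate, two-sided, with Benjamini-Hochberg adjustment over 21477 genes and a threshold of 0.05. A positive log2 fold change means higher with quercetin. Gene lists were fixed before the data were examined and tested with camera of limma at a preset inter-gene correlation of 0.01, two-sided, with a Benjamini-Hochberg family of 20 function lists and another of 17 cell type lists. The function lists were p53 targets, DNA repair, NRF2 targets, AhR targets, CAR and PXR targets, flavonoid conjugation and efflux, fatty acid oxidation and PPARA targets, cholesterol synthesis, fatty acid synthesis, lipid absorption and chylomicrons, bile acid handling, carbohydrate digestion and transport, mitochondrial respiration and biogenesis, cell cycle, endoplasmic reticulum stress, NF-kB and inflammation, interferon response, MHC class II, antimicrobial and mucosal defence, and circadian clock. The cell type lists covered enterocyte, goblet, Paneth, enteroendocrine, tuft, crypt base stem, smooth muscle, fibroblast, endothelial, T cell, B and plasma cell, macrophage and dendritic, pancreatic acinar, hepatocyte and adipocyte markers, and markers of the proximal and of the distal small intestine. Mast cell and erythroid lists had fewer than 4 measured members and were not tested. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, stand beside the preset camera result. For the list tests, 586 missing values were filled with the gene's mean. Members were also adjusted over their own list alone, which makes no allowance for the number of lists tested. A list score is the mean log2 ratio of the measured members in a mouse, and its difference between diets was tested by permutation of the diet labels (100000 resamples, two-sided), a test added after seeing the data. The share of variance between the diets was the sum of squares between groups over the total, with a one-sided permutation test of 100000 resamples. The Cy3 channel, which held the same pool on every array, was background corrected, quantile normalized and tested the same way as a negative control.

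Genes named in the text were chosen by a fixed rule, apart from examples of lists. It took up to 15 genes per direction with the largest change among those at adjusted p under 0.05; if fewer than 10 passed in a direction, the genes with the smallest unadjusted p there until 10 were named; always Cdkn1a, Mdm2, Ccng1, Cyp1a1, Nqo1, Hmox1, Gclc, Ugt1a1 and Abcg2 where measured; and the 2 members of each function list with the smallest unadjusted p. The rule gave 63 genes, of which 4 are not reported here. Outside the rule, Cd74, Ciita, Gzmb, Gzma, Cd8a, Cd4, Cd2, Col1a1, Col1a2 and Pdgfra were picked as examples of their lists after their values were seen, as were the markers named for detection or for the range of a score. Unnamed loci were left out of its first parts, which passed over 5 loci higher and 1 lower with quercetin. Ugt1a1 had no probe under that name among those kept.

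The arrays came on 3 slides with both diets on each: 4 HF and 4 HF-Q mice on the first, 4 and 3 on the second, and 4 and 4 on the third. The slide was read from the names of the scanner output, and each slide was scanned once. Between 50.0% and 57.8% of spots were well above background in Cy5, and the median Cy5 intensity per array was 93.9 to 122.6 on the linear scale. Array precision was limited by the number of arrays. No pair of arrays looked like a repeat of the same sample, since the highest correlation of an array's log2 ratios with any other array was 0.396 to 0.722 across genes.

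The fits were tested on simulated data for this comparison: residuals of the 21477 genes with arrays shuffled, and 500 genes changed at each fold over 10 draws. At adjusted p under 0.05 limma recovered 41.2% of genes changed 1.2-fold, 82.4% at 1.35-fold, 93.2% at 1.5-fold and 98.2% at 2-fold, and 2.11% of its calls were false. Changed genes of all these folds were in each draw together, which eases the adjusted threshold. Recovery of a few small changes alone would be lower and was not simulated. With no list changed, camera with the preset correlation called 4.6 function lists per draw on average and 8 at most, and none with an estimated correlation. When all members of the p53 list were raised 1.1-fold, camera called that list in 10 of 10 draws with either correlation.

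Alternatives were other background corrections, normalizations and filters, the mean of all probes of a gene, the Cy5 channel alone, the authors' log10 ratios and log2 table, the slide as a block and each slide alone, the replicate number as a block, other variance models and array weights. Pancreatic acinar and smooth muscle scores as covariates were added after seeing the data.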

Results

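Transcript levels were profiled in scrapings of the small intestine from mice fed a high-fat diet for 12 weeks, without quercetin (HF, 12 mice) or with 0.33% of the flavonol quercetin in the diet (HF-Q, 11 mice). Each mouse gave 1 array, on which its Cy5-labelled RNA was read against a Cy3-labelled pool of all mice, so every value is a log2 ratio to that pool. Of the genes on the array, 21477 were measured above background, 14088 of them with a gene name. All 12 enterocyte markers, among them Alpi, Vil1 and Sis, were well above background on all 23 arrays. Of the hepatocyte markers, Ahsg and Mup3 were above background on 0 arrays, Fgb and Hpx on 2 and Alb on 11, whereas Apoh, Cyp2e1, Fga, Serpina1a and Tat were on all 23.

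The comparison of HF-Q with HF asked what dietary quercetin does to the intestinal transcriptome, and in particular whether it leaves a trace of DNA damage. Differences of the named genes with small unadjusted p were small. Among those higher with quercetin, picked after their values were seen from the 10 with the smallest p, were Wfdc18 (log2 fold change 0.44 ± 0.11 SE), Klrd1, a receptor of natural killer and cytotoxic T cells (0.30 ± 0.076), and Cd96, another receptor of these cells (0.27 ± 0.076). Among those lower were P3h4, which takes part in collagen modification (-0.45 ± 0.10), Nt5e, the ecto-enzyme that makes adenosine from AMP (-0.49 ± 0.12), and the transcription factor Atf5 (-0.25 ± 0.056). None of these passed the test: limma found 0 genes higher and 0 lower at adjusted p under 0.05, 0 at adjusted p under 0.10, and a smallest adjusted p of 0.951. At an unadjusted p under 0.05 there were 452 genes higher and 520 lower, 972 in all, where 1073.85 would be expected by chance.

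Among the 10 named genes with the smallest unadjusted p in the higher direction, Wfdc18 averaged -0.23 ± 0.27 in HF (SD, n = 12) and 0.21 ± 0.27 in HF-Q (SD, n = 11) as a log2 ratio to the pool. Its unadjusted p in limma was 3.74e-04, and 11 of 11 HF-Q mice lay above the HF median. The probe lies on chromosome 11 of build mm9, from 83524751 to 83524810. Far2, which reduces fatty acyl-CoA to fatty alcohol (0.25 ± 0.066 SE), Dpcd (0.16 ± 0.045), Psd4 (0.20 ± 0.058) and Ercc3 (0.16 ± 0.046) also had all 11 HF-Q mice above the HF median, as did Klrd1 and Cd96. Tmem171 (0.24 ± 0.063), Cd200r2 (0.30 ± 0.079) and the aldo-keto reductase Akr1b10 (0.36 ± 0.10) completed the set. In the lower direction P3h4 averaged 0.26 ± 0.26 in HF (SD, n = 12) and -0.19 ± 0.25 in HF-Q (SD, n = 11), with an unadjusted p of 1.68e-04 in limma. Its probe lies on chromosome 11 from 100270063 to 100270122. Atf5 (unadjusted p = 1.70e-04; chromosome 7, 52067627 to 52067686), Maged2 (-0.32 ± 0.073 SE), Pmepa1 (-0.28 ± 0.073), Cnnm1 (-0.28 ± 0.074) and the nuclear import receptor Tnpo1 (-0.16 ± 0.043) had 11 of 11 HF-Q mice below the HF median. Gprc5c (-0.24 ± 0.064), Trim65 (-0.20 ± 0.056) and Rgs9 (-0.27 ± 0.076) were the others. Probes of Trim65 disagreed in sign, with 1 of 2 on the side reported, as did those of Rgs9, with 3 of 4. The genes of this paragraph were chosen by their p in these same mice. Their counts of HF-Q mice beyond the HF median follow largely from that choice and add no evidence.

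**Figure D1:**
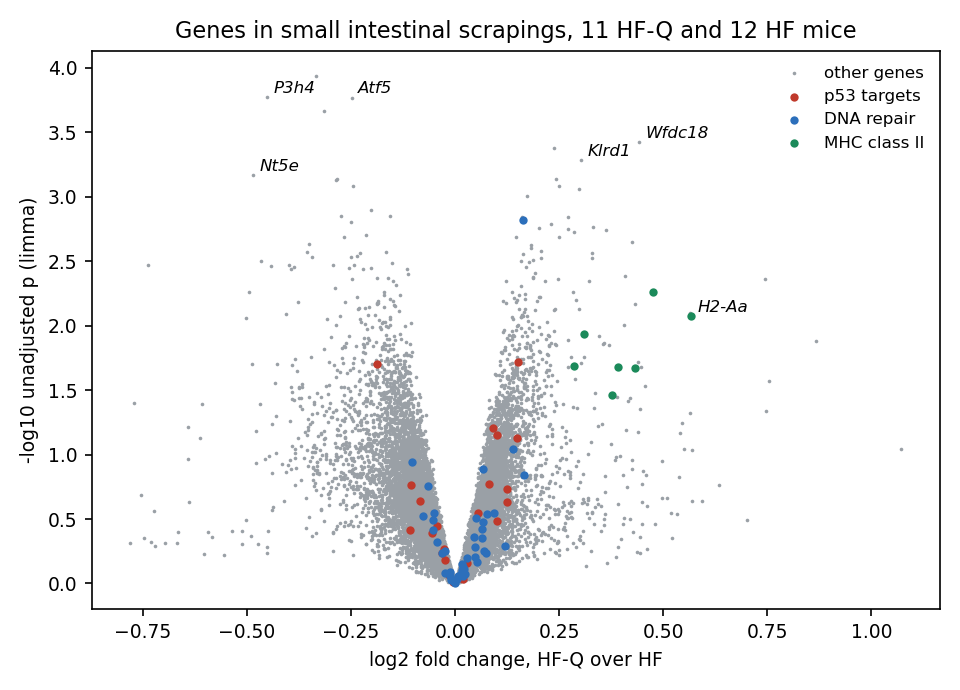
Each point is 1 of the 21477 genes, with the log2 fold change of HF-Q (11 mice) over HF (12 mice) on the x axis and minus log10 of the unadjusted limma p on the y axis. Coloured points are members of 3 lists; the 7 MHC class II genes all lie to the right, while p53 targets and DNA repair genes lie on both sides, and no gene reached adjusted p under 0.05.

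The question of genotoxicity was addressed with targets of p53, the transcription factor that is activated by DNA damage. Of the 27 measured targets, 14 were higher and 13 lower with quercetin, with a median log2 fold change of 0.0094 (camera adjusted p = 0.390; adjusted p = 0.800 with an estimated correlation). Cdkn1a, the cell cycle inhibitor that p53 induces (0.0094 ± 0.078 SE; chromosome 17, 29237377 to 29237436), Mdm2, the ubiquitin ligase that degrades p53 (-0.044 ± 0.047), and Ccng1 (0.15 ± 0.080) did not pass the test. The smallest unadjusted p values belonged to Polk, a translesion polymerase (0.15 ± 0.061), and Pmaip1, which encodes the pro-apoptotic protein Noxa (-0.19 ± 0.075), in opposite directions. No target passed over all genes tested, nor were any below 0.05 adjusted over the list alone. The 95% intervals of all 27 targets lay within 1.5-fold in either direction. The mean of the targets differed by 0.015 with the slide as a block and by 0.011, 0.060 and -0.019 within the slides.

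DNA repair genes gave a similar result, with 28 of 43 measured genes higher, 15 lower, and a median log2 fold change of 0.019 (camera adjusted p = 0.215; adjusted p = 0.800 with an estimated correlation). Ercc3, a helicase of nucleotide excision repair (0.16 ± 0.046 SE), and Polb, the polymerase of base excision repair (0.14 ± 0.079), had the smallest unadjusted p. No repair gene passed over all genes tested or adjusted over the list alone, and all 43 intervals lay within 1.5-fold. With the slide as a block the mean of the repair genes differed by 0.024, and within the slides by 0.046, 0.019 and 0.0055. The list reached adjusted p = 0.0105 in camera, with a median of 0.061, when pancreatic acinar and smooth muscle scores were added to the fit, a setting chosen after seeing the data; with an estimated correlation the adjusted p was 0.581. Over 17 alternatives the camera adjusted p of the list ranged from 0.0105 to 0.873.

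**Figure D2:**
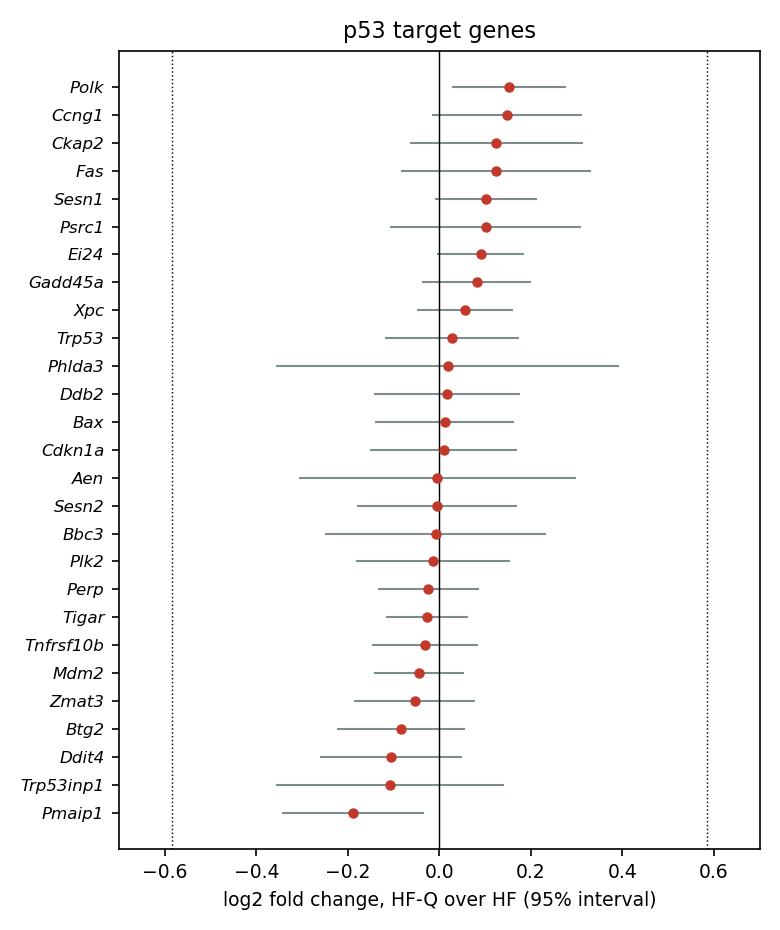
Log2 fold change of HF-Q (11 mice) over HF (12 mice) for the 27 measured p53 targets, ordered by value, with the 95% interval from limma as bars and dotted lines at 1.5-fold in either direction. All 27 intervals lie between the dotted lines, from Pmaip1 at -0.19 to Polk at 0.15.

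Among the lists of genes that respond to electrophiles and xenobiotics, NRF2 targets were higher as a group in camera with the preset correlation, and the other 3 lists did not pass. Of 23 NRF2 targets, which serve antioxidant defence, 20 were higher and 3 lower (median 0.038; camera adjusted p = 0.0324, and adjusted p = 0.797 with an estimated correlation). Gstm1, a glutathione transferase (0.37 ± 0.14 SE), Gclc, the catalytic subunit of glutathione synthesis (0.17 ± 0.072), and the quinone reductase Nqo1 (0.16 ± 0.077) stood against Me1, the NADPH-producing malic enzyme (-0.49 ± 0.16), and Hmox1 was close to 0 (0.019 ± 0.11, 1 of 2 probes on that side). The scanner file places the Gstm1 probe on chromosome 5 and the reference table places the gene on chromosome 3, so its identity is uncertain. The mean of the NRF2 targets differed by 0.060 with the slide as a block and by -0.010, 0.069 and 0.12 within the slides. The list no longer passed with the slide as a block (camera adjusted p = 0.0638), with the authors' log10 ratios (0.0617), with pancreatic acinar and smooth muscle scores in the fit (0.137, chosen after seeing the data) or within the first and second slides, and its adjusted p ranged from 0.00178 to 0.906 over the refits. Among 8 targets of the aryl hydrocarbon receptor 4 were higher and 4 lower (median 0.022; camera adjusted p = 0.390). Cyp1a1, its best-known target, had a log2 fold change of 0.57 ± 0.27 SE (unadjusted p = 0.0473 in limma; 10 of 11 HF-Q mice above the HF median), but its value was -0.27 within the second slide, and it was well above background on 6 of 12 HF and 10 of 11 HF-Q arrays. CAR and PXR targets, the receptors of drug metabolism, were 8 higher and 9 lower of 17 (camera adjusted p = 0.576, direction up as for the mean of 0.014, against a median of -0.0063). Akr1b7 (0.33 ± 0.10), the 1 member that passed adjusted over the list alone, and Abcc3 (0.17 ± 0.12) had the smallest unadjusted p. Genes for conjugation and efflux of flavonoids, such as the efflux pump Abcg2 (0.0029 ± 0.071) and the glycoside-cleaving lactase Lct (-0.31 ± 0.18), were 7 higher and 9 lower of 16 (median -0.0063; camera adjusted p = 0.681). Ugt1a1, Ugt1a2, Ugt1a7c and Ugt1a9 of that list had no probe under those names, so Ugt1a6a was its only Ugt1a gene measured. No gene of these lists passed over all genes tested.

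Lists of lipid metabolism went in both directions in camera with the preset correlation, and none passed with an estimated correlation or in the permutation of list scores. The permutation p of the score was 0.171 for fatty acid oxidation, 0.269 for lipid absorption and 0.238 for cholesterol synthesis. Each of these was 0.768 after adjustment over the function lists. Of 29 genes of fatty acid oxidation and PPARA targets, 25 were lower and 4 higher (median -0.092; camera adjusted p = 1.49e-05, and adjusted p = 0.797 with an estimated correlation). Acadvl, which oxidises very long chain fatty acids, had a log2 fold change of -0.13 ± 0.062 SE (unadjusted p = 0.0443 in limma; 9 of 11 HF-Q mice below the HF median). The list's mean differed by -0.14 with the slide as a block and by 0.029, -0.19 and -0.25 within the slides; within the first slide the median was -0.048 and the list did not pass (camera adjusted p = 0.906, the highest over the refits, against a lowest of 3.42e-07). With median centring, which moved the median of all genes to 0.049, the list's median was -0.0060 (camera adjusted p = 0.0104). Lipid absorption and chylomicron genes were lower in 18 of 22 (median -0.071, camera adjusted p = 0.0179, and adjusted p = 0.800 with an estimated correlation). Fabp2, an intestinal fatty acid binding protein (-0.22 ± 0.084), and the cholesterol exporter Abca1 (-0.25 ± 0.11) had the smallest unadjusted p, while the lowest member was at -0.37. The mean of the lipid absorption genes differed by -0.10 with the slide as a block and by -0.015, -0.22 and -0.10 within the slides. The list passed in 10 of 16 refits: with median centring its median was 0.031 (camera adjusted p = 0.173), and it did not pass with Cy5 alone (0.168), array weights (0.315), the authors' log2 table (0.152) or within the first slide, where the median was 0.0065 (0.906), and the third (0.154). The lowest adjusted p over the refits was 2.71e-04. Genes of cholesterol synthesis were higher in 18 of 24 (median 0.12; camera adjusted p = 0.00175, and adjusted p = 0.797 with an estimated correlation), with Fdft1, squalene synthase (0.21 ± 0.10), as an example. Their mean differed by 0.077 with the slide as a block and by 0.094, 0.11 and 0.032 within the slides, and within the third slide the list did not pass (camera adjusted p = 0.489, against 4.06e-07 at the lowest over the refits). Of 16 fatty acid synthesis genes 6 were higher and 10 lower (median -0.026; camera adjusted p = 0.681), and besides Me1 the smallest p was that of the carboxylase Acacb (-0.20 ± 0.11). None of the genes in these 4 lists passed over all genes tested or adjusted over the list alone.

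MHC class II genes, which present peptides to helper T cells, had the smallest camera p of the 20 function lists. All 7 were higher with quercetin, with a median log2 fold change of 0.39 (camera adjusted p = 3.57e-09). With an estimated correlation of the genes the list had an adjusted p = 0.289 (unadjusted p = 0.0144); that estimated correlation was 0.846. H2-Aa was 1.48-fold (log2 0.57 ± 0.20 SE; chromosome 17, 34421285 to 34421344), H2-DMa 1.39-fold (0.48 ± 0.16), Cd74, the invariant chain, 1.30-fold (0.38 ± 0.17), and Ciita, the transactivator of the class, 1.22-fold (0.29 ± 0.12). All 7 passed adjusted over the list alone and 0 passed over all genes tested. With so high a correlation, the 7 genes are not independent tests. The mean of the 7 genes was -0.26 ± 0.42 in HF mice (SD, n = 12) and 0.15 ± 0.31 in HF-Q mice (SD, n = 11). That difference of 0.40 had a permutation p of 0.0184, which is 0.367 after adjustment over the 20 lists, and 9 of 11 HF-Q mice lay above the HF median. It was 0.41 with the slide as a block and 0.51, 0.36 and 0.35 within the slides.

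Interferon response genes were higher in 16 of 21 (median 0.097, camera adjusted p = 0.00482, and adjusted p = 0.797 with an estimated correlation). The smallest unadjusted p belonged to Psmb9, a subunit of the immunoproteasome (0.28 ± 0.11 SE), and the peptide transporter Tap1 (0.30 ± 0.12), while the highest member was at 0.44. The mean of the interferon genes differed by 0.10 with the slide as a block and by 0.19, -0.039 and 0.13 within the slides. The list did not pass with pancreatic acinar and smooth muscle scores in the fit, chosen after seeing the data (median 0.055; camera adjusted p = 0.125) or within the second slide (median -0.075; adjusted p = 0.507, the highest over the refits, against a lowest of 3.31e-05). T cell markers were higher in 6 of 8 (median 0.19; camera adjusted p = 2.80e-04, and adjusted p = 0.603 with an estimated correlation). Granzymes Gzmb (0.42 ± 0.12) and Gzma (0.43 ± 0.15) and the co-receptor Cd8a (0.22 ± 0.082) passed adjusted over the list alone, with no allowance for the number of lists. Cd4 (-0.019 ± 0.077) and Cd2 (-0.025 ± 0.12) were near 0. The mean of the T cell markers differed by 0.18 with the slide as a block and by 0.28, 0.15 and 0.11 within the slides. Markers of B and plasma cells (3 of 7 higher, median -0.0033; camera adjusted p = 0.873) and of macrophages and dendritic cells (1 of 7 higher, median -0.070; camera adjusted p = 0.180) did not pass. NF-kB and inflammation genes were 12 higher and 7 lower (median 0.022; camera adjusted p = 0.390), with Il18 at 0.25 ± 0.15 and Cxcl10 at 0.21 ± 0.13. Antimicrobial and mucosal defence genes were 8 higher and 6 lower (median 0.094; camera adjusted p = 0.452), with the mucin Muc3 at -0.31 ± 0.13 and Lypd8 at 0.19 ± 0.11. No member of the lists in this paragraph passed over all genes tested.

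**Figure D3:**
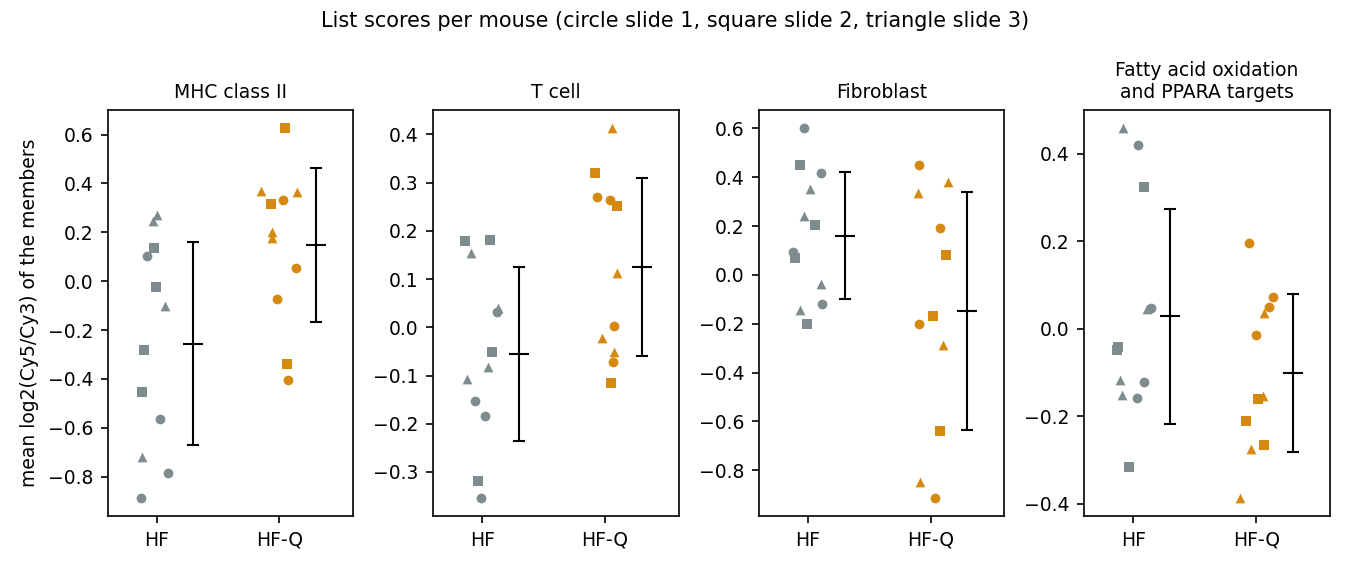
Mean log2(Cy5/Cy3) of the measured members of 4 lists in each of 12 HF and 11 HF-Q mice; marker shapes give the slide, and the bar beside each group is the mean ± SD. MHC class II values average -0.26 in HF and 0.15 in HF-Q with overlapping groups, and the other 3 lists overlap as well.

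Cell cycle genes were higher in 25 of 26, each by little (median 0.073; camera adjusted p = 0.0193, and adjusted p = 0.800 with an estimated correlation), as for the replication helicase subunit Mcm5 (0.14 ± 0.12 SE) and topoisomerase Top2a (0.16 ± 0.14). Their mean differed by 0.074 with the slide as a block and by 0.080, 0.037 and 0.098 within the slides, and the list did not pass within the first (camera adjusted p = 0.0893) and second slides (0.706), over a range of refits from 4.06e-07 to 0.706. Bile acid handling was 7 higher and 2 lower (median 0.11; camera adjusted p = 0.219). Slc51b, a subunit of the basolateral bile acid exporter (0.31 ± 0.12), and Fgf15, the ileal hormone that represses bile acid synthesis (-0.77 ± 0.36), went opposite ways, and Fgf15 was 0.25 within the first slide. Endoplasmic reticulum stress genes were 11 higher and 8 lower (median 0.050; camera adjusted p = 0.390), with Sdf2l1 at 0.24 ± 0.082 and Dnajb9 at -0.17 ± 0.056, the latter with 1 of 2 probes on that side. Carbohydrate digestion and transport were 6 higher and 6 lower (median -0.0030; camera adjusted p = 0.631), with the gluconeogenic Fbp1 at -0.28 ± 0.15. Mitochondrial respiration and biogenesis were 11 higher and 14 lower (median -0.0080; camera adjusted p = 0.681), with Atp5a1 at -0.077 ± 0.047 and the deacetylase Sirt1 at -0.068 ± 0.053. Circadian clock genes were 7 higher and 9 lower (median -0.048; camera adjusted p = 0.652), with Cry2 at -0.15 ± 0.10. Over all genes tested, as well as adjusted over each list alone, 0 members of these 6 lists passed.

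Among the other cell types, fibroblast markers were lower in 6 of 6 (median -0.31; camera adjusted p = 3.34e-04, and adjusted p = 0.603 with an estimated correlation). The collagens Col1a1 (-0.37 ± 0.17 SE) and Col1a2 (-0.37 ± 0.16) and the receptor Pdgfra (-0.31 ± 0.15) led the list. Its mean differed by -0.31 with the slide as a block and by -0.37, -0.37 and -0.21 within the slides. The fibroblast score averaged 0.16 in HF (SD 0.26) and -0.15 in HF-Q (SD 0.49). Of the HF-Q mice, 7 lay below the HF median and 4 above. The lowest scores were those of HF-Q replicates 1, 2 and 3 (-0.64, -0.85 and -0.91), which lay on different slides. Each value within a slide thus includes 1 of these low mice, and the difference without them was not tested. Smooth muscle markers were lower in 8 of 8 (median -0.22; camera adjusted p = 0.149), with a score that spanned 5.49-fold between mice. All 9 pancreatic acinar markers were lower (median -0.58; camera adjusted p = 0.180), over a range of 82.5-fold between mice, with a mean difference of -0.41, 0.22 and -1.32 within the slides, and the 6 Paneth markers had 1 higher (median -0.20; camera adjusted p = 0.438). For epithelial types the medians were -0.050 for enterocytes (adjusted p = 0.539), -0.077 for goblet cells (0.438), -0.030 for enteroendocrine cells (0.703), -0.099 for tuft cells (0.149) and -0.0057 for crypt base stem cells (0.817), with the camera adjusted p in brackets. The remaining medians were -0.085 for endothelium (adjusted p = 0.630), -0.037 for hepatocytes (0.703), 0.055 for adipocytes (0.703), -0.064 for the proximal small intestine (0.703) and 0.31 for the distal small intestine (0.180). The 5 distal markers were all members of the bile acid handling list too, so sampled region and bile acid handling cannot be told apart from them. No marker of these lists passed over all genes tested.

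Over the whole profile, 4.13% of the variance lay between the diets, where permuted labels gave 4.55% on average (one-sided permutation p = 0.521). The 95% interval of the fold change lay within 1.5-fold for 20862 genes (97.1%) and within 2-fold for 21371 (99.5%), and 26 genes had an estimate beyond 1.5-fold. Fgf15 was among the latter. With the slide as a block limma called 0 genes, and within each slide 0. In the Cy3 reference pool, limma called 0 genes at adjusted p under 0.05, with 562 at an unadjusted p under 0.05. The replicates were separate mice.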

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

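The tissue mix covariates (pancreatic acinar and smooth muscle scores) and the permutation of list scores were chosen after seeing the data. Aquantile scaling between arrays leaves log ratios as they are, tests nothing here and is in no count. Under all 17 other alternatives 0 genes were called by limma between the diets, with a smallest adjusted p from 0.262 to 0.981. The share of variance was 4.00% to 4.86% under 5 alternatives, with no permutation p under 0.443, and the reference channel had 0 calls under 3. The replicate numbers do not pair the mice 1 to 1: 5 of 11 pairs correlated above 0.1 (range -0.347 to 0.394), and 1 mouse correlated best with its own number. A trend along the numbers escapes that comparison. The crypt base stem score was -0.51 to -0.17 in HF replicates 1 to 4 and 0.039 to 0.45 in HF replicates 7 to 12. In HF-Q it was -0.78 to -0.32 in replicates 1 to 3 and 0.26 to 0.31 in replicates 7 to 11. That score correlated with the first principal component at r = 0.958. The cause was not tested. With the replicate block 0 genes and 7 lists were called, and DNA repair passed (median 0.027, adjusted p = 0.0374; adjusted p = 0.740 with an estimated correlation).

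Of 19 alternatives for the function lists, 15 called between 5 and 9 lists, against 7. Slide 1 alone called 3, slide 2 alone 5 and slide 3 alone 9; the cause was not tested. Camera with an estimated correlation, fry and the permutation of list scores each called 0. MHC class II was called in 16 of 16 refits with the preset correlation, with medians from 0.34 to 0.50. Fatty acid oxidation and cholesterol synthesis were called in 15 each, cell cycle and interferon response in 14 each, and NRF2 targets (with the replicate block, adjusted p = 0.0774) and lipid absorption in 10 each. Carbohydrate digestion was called in 2 refits in opposite directions (median -0.28 within slide 2 and 0.0098 within slide 3), and CAR and PXR targets, NF-kB and antimicrobial genes in 1 each, within slide 3. The p53 median ranged from -0.037 within slide 3 to 0.080 within slide 2, with -0.0012 for array weights and 0.075 for median centring, and no alternative gave the list an adjusted p under 0.215. DNA repair stayed positive (adjusted p 0.0105 to 0.873), and passed with the tissue mix covariates (median 0.061; adjusted p = 0.581 with an estimated correlation) besides the replicate block (adjusted p = 0.740 with an estimated correlation); the cause was not tested.

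None of the named genes passed in any refit, and 21 of 941 values had the other sign; the cause was not tested. Within slide 1 these were Hmox1 (-0.069), Gclc (-0.13), Abcc3 (-0.12), Fgf15 (0.25) and Il18 (-0.15). Within slide 2 they were Cyp1a1 (-0.27), Hmox1 (-0.088) and Abcg2 (-0.011), and within slide 3 Cdkn1a (-0.0026), Abcg2 (-0.044), Polb (-0.038), Abca1 (0.13), Atp5a1 (0.016), Muc3 (0.056) and Cry2 (0.015). Median centring turned Mdm2 (0.041) and Atp5a1 (0.031), Cy5 alone Trim65 (0.0019), and the tissue mix covariates Cdkn1a (-0.025). Abcg2 turned with the replicate block (-0.019) and array weights (-0.0053). The filter kept 52.5% of probes as well above background. With no filter (59 values), or with probes above background on every array (56 values), 0 of the values had the other sign. That was nearly fixed in advance, since a filter on dim probes mostly leaves the brightest probe of a gene in place. Refits with another variance model (59 values) leave fold changes as they are, so they could not turn a sign.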

Other observations

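For the macrophage and B cell scores, the slide and the estimated correlation, the outcome that would decide was written down only after the results were seen. Camera with an estimated correlation and the fit with the slide as a block had been planned. The tissue mix covariates were chosen after seeing the data, and the principal components and score ranges were examined without a plan. Scores of pancreatic acinar markers such as Cpa1 and Pnlip spanned 82.5-fold over the 23 mice, Paneth markers such as Lyz1 6.15-fold, smooth muscle markers 5.49-fold and distal small intestine markers 4.23-fold. The first principal component held 23.1% of the variance and did not separate the diets (permutation p = 0.970). Of 5 components examined, the fifth, with 5.43% of the variance, differed between the diets (permutation p = 0.00755, adjusted p = 0.0377 over the 5). Its score averaged 3.98 ± 7.21 in HF (SD, n = 12) and -4.34 ± 6.94 in HF-Q (SD, n = 11), with 9 of 11 HF-Q mice below the HF median. The difference was -11.0 and -13.9 within slides 1 and 3 and 1.03 within slide 2, so it did not hold within every slide.

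Of 37 list scores, that of the hepatocyte markers had the highest Pearson correlation with the fifth component (r = 0.556, permutation p = 0.00543, adjusted p = 0.201 over the 37 relations; Spearman rho = 0.548, permutation p = 0.00771, adjusted p = 0.143), which did not pass. The r was 0.474 without the 2 mice farthest from the median hepatocyte score, 0.583 within HF and 0.592 within HF-Q, and 0.00267, 0.879 and 0.756 within the slides. The hepatocyte list itself did not pass between the diets (median -0.037, camera adjusted p = 0.703). By rank, the T cell score had a larger correlation with this component, of the other sign (Spearman rho = -0.578, permutation p = 0.00472, adjusted p = 0.143). It did not pass either. The Pearson r of the T cell score was -0.482 (permutation p = 0.0185, adjusted p = 0.237), and -0.448, -0.678 and -0.619 within the slides. Within HF and HF-Q that r was -0.380 and -0.255.

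MHC class II genes were higher with quercetin by 0.40 on the log2 scale as a mean of 7 genes. More macrophages or B cells would raise their markers as well, yet the diet difference of the MHC class II score exceeded that of each marker score. The lower 95% bound of that excess was 0.084 at the least, with no adjustment for choosing this list from 20. The comparison takes a change in cell number to move both scores by the same log2 amount, which was not tested. In HF the SD was 0.42 for the MHC class II score, 0.13 for the macrophage and dendritic score and 0.40 for the B and plasma cell score. A rise of macrophages that moves their markers less is therefore not excluded. The macrophage and dendritic score averages 7 markers of both cell types, so a rise of dendritic cells alone could be hidden in it and stays open. The diets were nearly balanced over the slides, so the slide as a block (0.41) could hardly move the value and tests little. The same sign within all 3 slides argues against a slide difference. The 100 splits of the mice, here and below, include the real one, which counts as matching itself. In 18 of 100 splits some function list had a camera adjusted p as small as the real one (minus log10 of 8.45, highest other 15.4), so chance was not excluded. For the MHC class II score alone, which was singled out as the list with the smallest p of 20, 4 of 100 splits gave a difference as large (highest other 0.50). A candidate explanation besides chance is that MHC class II genes follow the T cell genes, with which they share 0 members: over the 23 mice both scores had Pearson r = 0.679 (permutation p = 3.90e-04, adjusted p = 3.90e-04 over 3 relations).

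The same 2 scores had Spearman rho = 0.708 (permutation p = 2.40e-04, adjusted p = 2.40e-04), r = 0.664 without the 2 mice farthest from the median T cell score, 0.684 within HF (n = 12, permutation p = 0.0173) and 0.461 within HF-Q (n = 11, permutation p = 0.158). Within the slides r was 0.732, 0.801 and 0.422. MHC class II and interferon response scores had r = 0.766 (permutation p = 3.00e-05, adjusted p = 4.50e-05), rho = 0.807 (permutation p = 1e-05, the smallest the resamples can give, adjusted p = 1.5e-05) and r = 0.784 without the 2 farthest mice. Within HF and HF-Q that r was 0.725 and 0.846, and within the slides 0.957, 0.653 and 0.713. With the T cell score as a covariate the MHC class II difference between diets was 0.19 (95% interval -0.11 to 0.49).

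Fibroblast markers were lower by 0.31 as a mean of 6 genes, and 6 of 100 splits gave a difference as large in either direction, up to 0.44, so chance was not excluded. Fibroblast and smooth muscle scores moved together over the 23 mice (Pearson r = 0.890, permutation p = 1e-05, adjusted p = 3.00e-05; Spearman rho = 0.941, permutation p = 1e-05, adjusted p = 1.5e-05; 1e-05 is the smallest the resamples can give). The r was 0.907 without the 2 mice farthest from the median smooth muscle score, 0.858 within HF and 0.953 within HF-Q, and 0.908, 0.971 and 0.896 within the slides. Less muscle wall in the HF-Q scrapings may account for part of the difference: with the smooth muscle score as a covariate it was -0.18 (95% interval -0.33 to -0.023). That interval reaches from near 0 to the full difference, which keeps this open.

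The 7 function lists called with the preset correlation were matched or exceeded in 34 of 100 splits of the mice, with 12 lists in the highest other, so chance was not excluded. With an estimated correlation 0 function lists were called, and shuffled residuals with no changed list gave 4.6 calls on average with the preset correlation. Genes of a list varied together more than the preset correlation of 0.01 assumes. The estimate was above it for every function list, from 0.020 for AhR targets to 0.85 for MHC class II. Among the 7 called lists the lowest was 0.12, for NRF2 targets. For the 2 cell type lists, 66 of 100 splits called as many and the highest other called 9. Genes at an unadjusted p under 0.05 were as many as the real 972 in 41 of 100 splits. The count ran from 198 to 3650 over the other splits, and the cause of that wide range was not tested. For the real 0 genes at adjusted p under 0.05 (highest other 2) and the 0 genes of the reference channel (highest other 2), the count of 100 of 100 splits was fixed, since any split calls at least 0, and says nothing about chance. With the tissue mix covariates 2543 genes had an unadjusted p under 0.05, 6 of 100 splits gave as many and the highest other gave 3396, so chance was not excluded there either.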
